A study of Pseudomonas aeruginosa PA14 with 4 samples.

How the data were processed

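RNA sequencing counts were available for 4 libraries of P. aeruginosa PA14, grouped by the treatment label into 2 untreated libraries and 2 given 8 µM H2O2 for 5 minutes. RNA was isolated with a bacterial TRIzol kit and libraries were made with a stranded mRNA kit, per the labels' protocols. The deposited values are raw read counts per gene, made by the authors with featureCounts 2.0.3, per the file headers. The headers record gene features, assignment of a read to the gene with the largest overlap, and no option for strand, for reads that map to several places or for read pairs. Counting was therefore not strand-specific although the kit was stranded, and genes with near-identical copies lose reads that map to both. One file of first reads entered each table, per the file headers. STAR, SAMtools, Subread, edgeR and limma are also listed, per the submitters' processing notes, without versions or roles. Aligner settings are not given in the sources used here. The tables name the sequence CP000438.1, and all coordinates are 1-based positions on it.

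Locus tags were looked up in a RefSeq gene table of another PA14 assembly (ASM6044630v1), which uses other tags. Of 5977 tags, 0 matched, and no names were assigned by position or order. The gene lists fixed before the data were examined, which were written as gene symbols, could not be applied by symbol, so 0 lists were tested. Ribosomal and transfer RNA genes could not be told from the others for the same reason.

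Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr defaults, which kept 5926 genes, TMM factors, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. No covariate was fitted. CPM values use TMM-scaled library sizes. The standard error is the fitted log2 fold change over the square root of the F statistic. An exact permutation test of a single gene with 2 libraries against 2 cannot go below p = 0.333, so none is given. This test, its samples and the alternatives to it were fixed before the data were examined. They were DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's exact test, other scaling factors, other count filters, the replicate number as a block and each library left out. The rule for naming genes took called genes with the largest changes, a fixed set of oxidative stress and reference genes by symbol, and the members of each gene list with the smallest p-values. It named none, because 0 genes were called and symbols could not be matched. The rule also allowed the fro operon to be matched by PA14 locus tags. That match was not made, so its genes are not reported. The 4 genes given by locus tag are those with the 2 smallest p-values in each direction and were chosen after their values were seen.

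The separation counts were also chosen after the data were examined. A 2-fold separation was tried first, and 4-fold was taken because the 2-fold counts (25 genes higher and 9 lower) did not exceed those of simulated data without change (39 to 46 higher and 36 to 56 lower). A gene counted as separated when every library of a group exceeded every library of the other by 4-fold in log2 CPM (prior count 2), with a mean count of at least 50 over the libraries. Separated genes in the same direction with at most 300 bp between them were joined into 1 locus.

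The procedures were tested on simulated data. In 5 simulations of this comparison over 5926 genes, with 200 changed genes each, edgeR's quasi-likelihood test called 0.8% of genes changed 2-fold, 20.4% of those changed 4-fold, 74.4% of those changed 8-fold and 100% of those changed 32-fold. DESeq2 called 6.8%, 51.2%, 94% and 100% of them, with 31.4 unchanged genes called per simulation against 7.2 for the quasi-likelihood test. The slope of fitted on true log2 fold change was 0.99. The simulated spread came from dispersions estimated in these 4 libraries and shrunken toward a common trend. The adjusted threshold is looser with 200 changed genes than with few, so the shares recovered hold for that number of changed genes. None of the 5 separated genes fitted at 32-fold or more was called by the quasi-likelihood test in the deposited counts.

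Library totals ranged from 17200780 to 22621972 assigned reads, so replicate spread and not counting error limited most values. The chi-square per degree of freedom between libraries of a group was 337 for the untreated and 1014 for the H2O2 libraries, far above counting error. No library was therefore treated as a second sequencing run of another. These values cannot tell separate cultures from separate preparations of the same culture. TMM factors ranged from 0.946 to 1.06.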

Results

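RNA was sequenced from mid-log cultures of Pseudomonas aeruginosa PA14, a virulent laboratory strain of an opportunistic pathogen. The wild-type cells had either received no treatment or been exposed to 8 µM hydrogen peroxide (H2O2, an oxidant that damages DNA, thiols and iron-sulphur clusters) for 5 minutes. The comparison addresses which transcripts differ shortly after this exposure. There were 2 libraries per group and 4 in all. The count tables assigned 22621972 and 17200780 reads to genes in untreated replicates 1 and 2, and 19388446 and 21086801 in H2O2 replicates 1 and 2. Of the 5977 annotated genes, between 12 and 14 had no read in a given library, and the median gene had between 460 and 667 reads. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Genes carry locus tags without names, and 0 of the 5977 tags matched the RefSeq gene table used here. Genes are therefore described by position on the PA14 chromosome sequence CP000438.1, and functions are not stated.

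After 8 µM H2O2, a small set of loci was far higher in both treated libraries than in either untreated library. In 10 genes at 6 loci, the lower H2O2 library was at least 4-fold above the higher untreated one, and in 6 of these genes at least 8-fold. A single locus of 2 genes was at least 4-fold lower in both treated libraries. Groups of 2 unchanged libraries do not overlap with a probability of 0.333, before any fold is required. This 4-fold rule was chosen after the data were examined. Without covariates, none of the 12 genes passed edgeR's quasi-likelihood test over all genes, as given after the values. Values are normalised read counts (CPM, with library sizes scaled by edgeR's TMM factors), given as mean ± SD over 2 libraries per group, with fold changes from the fitted model.

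By fitted fold change, the 5 highest of the separated genes lay in 3 pairs of adjacent genes. At positions 4722774 to 4724457 on the minus strand, gene PA14_53300 (600 bp, 4723858 to 4724457) had 13.4 ± 0.567 CPM in untreated cells and 1177 ± 228 CPM after H2O2 (SD, n = 2 per group). Its log2 fold change was 6.46 (SE 0.504), or 88.0-fold. The neighbouring 951 bp gene (4722774 to 4723724) had 17.9 ± 0.168 CPM untreated and 1403 ± 612 CPM after H2O2, or 78.4-fold more. At 1866255 to 1867277, gene PA14_21530 (516 bp, minus strand, 1866762 to 1867277) had 3.83 ± 0.228 CPM in untreated cells and 326 ± 109 CPM after H2O2. Its log2 fold change was 6.41 (SE 0.528), or 84.9-fold. The 504 bp gene beside it lies on the plus strand and had 8.30 ± 0.441 CPM untreated and 91.2 ± 41.9 CPM after H2O2. Reads were counted without regard to strand, so reads of this gene and reads running on from its opposite-strand neighbour cannot be told apart.

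The largest fitted fold change of the genes tested was at 5442038 to 5444184 on the minus strand. The 1542 bp gene there (5442643 to 5444184) stood at 21.9 ± 0.291 CPM in untreated cells and 3030 ± 2940 CPM after H2O2, a 138-fold difference. The 552 bp gene beside it had 5.42 ± 0.678 and 387 ± 470 CPM, a 71.4-fold difference. As a ratio, the treated libraries differed more in these genes than in the other separated ones. H2O2 replicate 1 had 951 and 54.9 CPM for these 2 genes and H2O2 replicate 2 had 5109 and 720 CPM.

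A further pair of genes was already abundant in untreated cells. At 156164 to 158437 on the plus strand, a 564 bp gene had 1601 ± 476 CPM untreated and 13251 ± 5292 CPM after H2O2 (8.28-fold). The 1566 bp gene that follows it had 307 ± 21.3 and 6786 ± 5924 CPM (22.1-fold). The former was the most abundant gene of H2O2 replicate 2, at 1.80% of its assigned reads. The remaining higher loci were single genes. The 447 bp gene at 271601 to 272047 on the minus strand was 9.69-fold higher, and the 231 bp gene at 3507877 to 3508107 on the plus strand was 7.31-fold higher. Both had more CPM in H2O2 replicate 1 than in H2O2 replicate 2 (184 against 66.9, and 116 against 51.2).

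The lower locus held 2 consecutive plus-strand genes at 1698525 to 1699587. Gene PA14_19680 (390 bp, 1698525 to 1698914) had 23.0 ± 0.734 CPM in untreated cells and 3.73 ± 0.283 CPM after H2O2, a log2 fold change of -2.62 (SE 0.364). Gene PA14_19690 (687 bp, 1698901 to 1699587) had 57.6 ± 1.30 CPM in untreated cells and 9.19 ± 2.05 CPM after H2O2, a log2 fold change of -2.65 (SE 0.386). The annotations of these genes overlap, so their reads are not fully separable. The value of PA14_19680 after H2O2 rests on 78 and 79 reads.

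**Figure D1:**
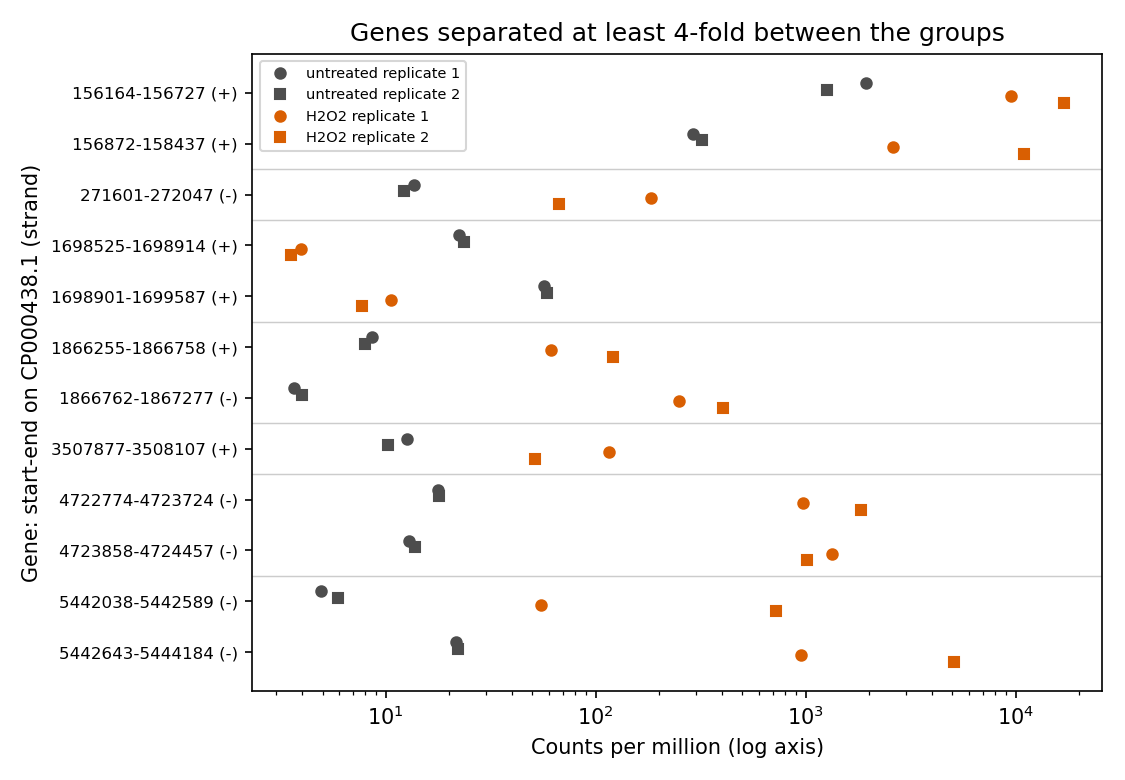
Normalised read counts (CPM, log axis) of the 12 genes whose groups were separated at least 4-fold, one row per gene with its start, end and strand on CP000438.1; each point is 1 library, circles are replicate 1 and squares replicate 2, and grey lines part the loci. In 10 genes both H2O2 libraries lie to the right of both untreated libraries, and in the 2 genes between 1698525 and 1699587 they lie to the left.

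None of these genes passed the quasi-likelihood test of edgeR across the genome, fitted without covariates. With the replicate number as a block, the test called 12 genes higher and 3 lower, among them the 12 separated genes. The labels do not state that same-numbered libraries are paired. Of 5926 genes tested, 0 were called higher and 0 lower at a Benjamini-Hochberg adjusted p of 0.05. An unadjusted p under 0.05 was found in 131 genes, 98 of them with more CPM after H2O2. That is fewer than evenly spread p-values would give over 5926 genes. The smallest edgeR adjusted p was 0.122, for PA14_53300 and PA14_21530, and that of PA14_19680 and PA14_19690 was 0.677. limma-voom also called 0 genes. Its adjusted p was 0.0568 for PA14_53300 and PA14_21530, and 0.606 for PA14_19680 and PA14_19690. The exact test of edgeR called 10 higher and 3 lower, and DESeq2 called 38 higher and 3 lower. All 12 separated genes were among the calls of the exact test and of DESeq2. Without H2O2 replicate 2 the quasi-likelihood test called 87 genes higher and 11 lower, and without H2O2 replicate 1 it called 6 higher and 0 lower. With no change simulated at the observed dispersions, DESeq2 still called between 7 and 10 genes higher and between 3 and 17 lower, the exact test between 3 and 9 higher and between 1 and 7 lower, and the quasi-likelihood test between 0 and 2 higher and 0 lower. In the same 5 simulations, 2 to 5 genes were separated 4-fold in the higher direction and 0 to 6 in the lower, so the 2 lower genes do not exceed that range. At 2-fold, the simulations separated more genes in each direction than the deposited counts did. The simulated spread therefore differed from that of the deposited counts, which limits what the range can show. The 4-fold rule was taken after this 2-fold comparison, so setting its counts against the same simulations is no independent test. The simulations also drew genes independently and gave all libraries the same dispersion for a gene.

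The treated libraries differed more from each other than the untreated ones did. Over all 5485 genes with a mean count of at least 50, the separated genes included, the log2 difference between the H2O2 libraries had an SD of 1.18, against 0.624 between the untreated ones. H2O2 replicate 1 was at least 2-fold above the other 3 libraries in 305 genes and at least 2-fold below them in 220. The corresponding numbers were 72 and 103 for H2O2 replicate 2, 18 and 38 for untreated replicate 1, and 21 and 18 for untreated replicate 2. Of the 41 genes called by DESeq2, 20 had H2O2 replicate 1 at least 2-fold above the higher untreated library and H2O2 replicate 2 less than 2-fold above it.

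**Figure D2:**
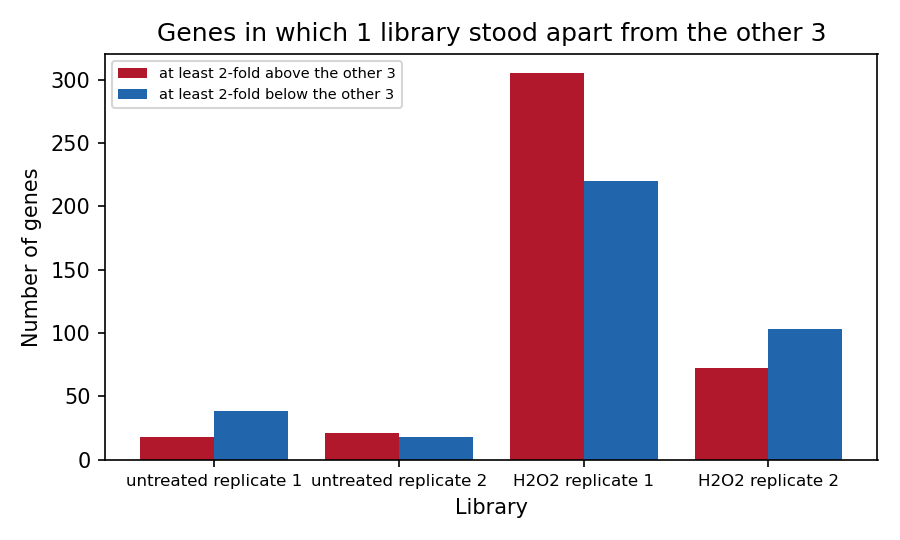
Number of genes (of 5485 with a mean count of at least 50) in which 1 library stood at least 2-fold above (red) or below (blue) the other 3. H2O2 replicate 1 stood apart in 305 and 220 genes, more than any other library.

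When each H2O2 library was set against the untreated library of the same replicate number, which the labels do not state to be paired, the ratios were nearly unrelated across genes, with a Pearson correlation of 0.036 (genes are not independent replicates). At least 4-fold higher values occurred in 149 genes in number 1 and in 25 genes in number 2, and 11 genes were shared. At least 4-fold lower values occurred in 37 and 18 genes, of which 3 were shared. PA14_53300 was 102-fold higher in number 1 and 73.3-fold in number 2, and PA14_21530 66.0-fold and 98.4-fold.

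**Figure D3:**
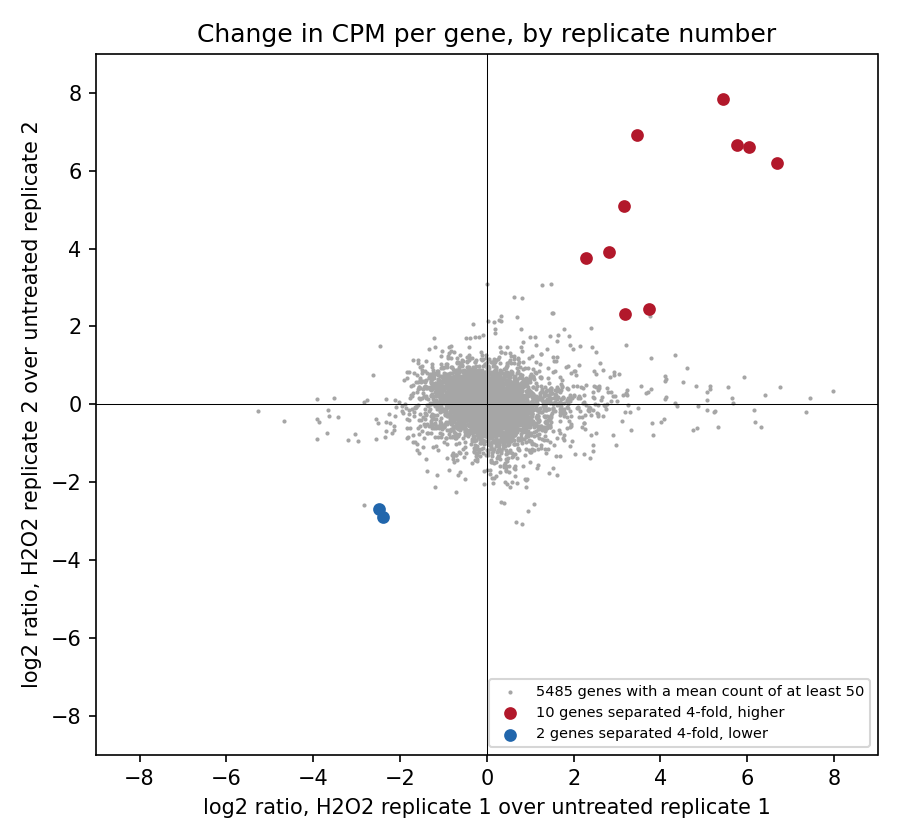
Change per gene in replicate number 1 (x axis) and number 2 (y axis), as the log2 ratio of H2O2 over untreated CPM; grey points are 5485 genes, red points the 10 genes separated 4-fold in the higher direction and blue points the 2 in the lower. The red points lie in the upper right, while many grey points spread along the x axis only.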

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

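The separation counts, their alternatives and DESeq2 with a library left out were chosen after the data were examined; the other alternatives were planned. The quasi-likelihood count of 0 genes in each direction was also 0 with DESeq2 size factors, library size only, upper quartile factors, no filter, the stricter filter (50 reads in 2 libraries) and limma-voom. It became 38 higher and 3 lower with DESeq2, and 10 and 3 with edgeR's exact test, with identical counts at 2-fold or more. Leaving out 1 library gave 0 to 87 genes higher and 0 to 11 lower, at 2-fold or more as well. It was 6 higher and 0 lower without H2O2 replicate 1, 87 and 11 without H2O2 replicate 2, and 0 without either untreated library; the lone library of a group is then assumed to vary like the other group. All 6 calls made without H2O2 replicate 1 were also made without H2O2 replicate 2. DESeq2 called 10 higher and 0 lower without untreated replicate 1, 17 and 0 without untreated replicate 2, 35 and 43 without H2O2 replicate 1, and 248 and 165 without H2O2 replicate 2. The cause was not tested.

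With the replicate block, 12 genes were called higher and 3 lower, all at 2-fold or more, and these included the 12 separated genes. The labels give no shared day or batch, so the libraries share only a number; the difference between replicates 2 and 1 correlated across genes between the groups with r = 0.451. The 10 higher and 2 lower genes separated 4-fold became 25 and 9 at 2-fold and 6 and 0 at 8-fold. They stayed between 9 and 11 higher and 2 and 3 lower under the other scalings and filters and within replicate numbers. With fewer libraries to separate they became 11 and 6 without untreated replicate 1, 17 and 2 without untreated replicate 2, 20 and 9 without H2O2 replicate 1, and 118 and 28 without H2O2 replicate 2. Over 13 alternatives, the fold changes of PA14_53300, PA14_21530, PA14_19680 and PA14_19690 kept their sign, with adjusted p from 1.1e-35 (DESeq2) to 1.0. Scaling by library size only shifted the median log2 fold change by 0.12. Removal of stable RNA genes and the tests of gene lists were not run, because genes could not be matched to symbols.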

Other observations

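H2O2 replicate 1 was at least 4-fold above every other library in 93 genes at 47 loci, and at least 4-fold below them in 22 genes at 12 loci. H2O2 replicate 2 lay above both untreated libraries in 37 of the 93 genes, below both in 21 and between them in 35. Being 4-fold above H2O2 replicate 2 was part of the choice, which leaves out genes about equally high in both treated libraries. These counts are shaped by that choice. The longest such locus, 9 consecutive minus-strand genes at 1802423 to 1816675, summed to 2370 CPM in H2O2 replicate 1, against 117 and 284 CPM in the untreated libraries and 269 CPM in H2O2 replicate 2. A locus of 8 genes at 903291 to 912510 summed to 3347 CPM in H2O2 replicate 1 and to at most 137 CPM elsewhere. A locus of 3 genes at 3559479 to 3561732 summed to 338 CPM there and to 4.85 to 6.71 CPM elsewhere, a 50.4-fold excess over the nearest library. This locus and the pair at 810876 to 812617 (2981 CPM against 16.4 to 132) both hold neighbouring genes of 1218 and 489 bp on the minus strand, and whether they share reads was not tested.

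In the other direction, 5 plus-strand genes at 1183607 to 1191250 summed to 238 CPM in H2O2 replicate 1, 1447 and 6841 CPM in the untreated libraries and 4121 CPM in H2O2 replicate 2. A locus of 3 genes at 6471293 to 6474136 stood at 10.1 CPM in H2O2 replicate 1 and at 127 to 253 CPM in the other libraries.

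In the paragraphs that follow, the tests of counting noise, gene length, a response of like size and replicate number were chosen after the result was seen. The first pattern is that H2O2 replicate 1 stands apart. Counting noise is argued against by same-strand neighbours within 50 bp, whose deviations correlated with r = 0.825 over 1781 pairs. The same pairs correlated with r = 0.839 for the difference between the untreated libraries, so the value is not particular to H2O2 replicate 1. A loss or gain of RNA by gene length is argued against by a Spearman rho of -0.013 over 5485 genes. A response to H2O2 of like size in both treated libraries was examined in 117 genes. In these, H2O2 replicate 1 was at least 4-fold above both untreated libraries. They were chosen without regard to H2O2 replicate 2, with filter and scaling taken over all libraries. Their median log2 difference from the untreated mean was 3.21 in H2O2 replicate 1 and 0.358 (SD 1.60 over genes) in H2O2 replicate 2. The latter library lay above both untreated libraries in 61 of them, at least 4-fold in 10, and below both in 21. Genes picked as high in H2O2 replicate 1 tend to fall back in another library by selection alone. Genes picked by H2O2 replicate 2 in a like way, with H2O2 replicate 1 left out of filter and scaling, were counted and were fewer. Their values in H2O2 replicate 1 were not summarised, so the fall-back could not be compared in both directions. The values above therefore do not decide about a response of like size. A weaker response among these 117 genes in H2O2 replicate 2 remains open and was not tested. So does a difference in cell state, exposure, preparation or labelling of H2O2 replicate 1. The separated genes were not uniformly lower in H2O2 replicate 2. The 1542 bp gene at 5442643 to 5444184 had 951 CPM in H2O2 replicate 1 and 5109 CPM in H2O2 replicate 2. PA14_53300 had 1338 and 1016 CPM.

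The second pattern is that more genes were separated by replicate number than by treatment. Whole profiles did not group that way for the replicates numbered 1. By Pearson r of log2 CPM, untreated replicate 1 was nearer untreated replicate 2 (0.970) and H2O2 replicate 2 (0.950) than H2O2 replicate 1 (0.939). H2O2 replicate 2 was nearest untreated replicate 2 (0.973). Untreated replicate 1 with H2O2 replicate 1 were separated 4-fold from the replicates numbered 2 in 26 genes, against 12 genes for treatment and 0 for the crossed split of the 4 libraries. Of the 26, 19 were higher and 7 lower in the replicates numbered 2, and no simulation without change was run for this split. A shared day or batch of same-numbered libraries is a candidate explanation, and the difference between replicates correlated between the groups with r = 0.451. With only 2 numbers such a correlation has an even chance of either sign, so a batch and chance cannot be told apart.

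The third pattern concerns the counting. Facing genes on opposite strands within 50 bp moved together, with r = 0.611 over 426 pairs for the fitted log2 fold change. If reads counted without regard to strand caused this, facing pairs over 150 and up to 500 bp apart should correlate less. They did, with r = 0.334 over 112 pairs, a difference of 0.277 (two-sided permutation p = 0.061, 10000 permutations; bootstrap interval 0.041 to 0.553). The interval excludes 0 while the permutation test misses the threshold, so whether spill-over between strands contributes stays open.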
